A study of Rattus norvegicus with 16 samples.

How the data were processed

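The samples were 16 cultures of primary rat hippocampal neurons in 4 groups of 4, hybridised to 8 Agilent rat arrays in 2 dyes. The group of each sample was taken from its source label and title. Another label field described adult brain tissue of hormone-treated animals, contradicted the culture protocol and the study design, and was not used. The Cy3 samples were replicates 1 and 3 and the Cy5 samples replicates 2 and 4 of each group, and the array and slide of each sample were read from the file headers. The intensity values in the scanner output are, per the file headers, mean spot pixel intensities and median local backgrounds from Agilent Feature Extraction 10.7.3.1, with no normalization. The same files hold a processed intensity that, per the file headers, was background-subtracted, detrended and dye-normalized by linear and lowess steps within the array. The deposited series matrix holds log2 values of the median spot signal minus the median background, minus the median of the column; regression on values recomputed from the scanner output gave a slope and an r of 1.

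For each array the background was corrected by normexp with an offset of 50, the dyes were balanced by loess with control spots at weight 0, and arrays were aligned by Aquantile normalization in limma 3.58.1 (with statmod 1.5.0) in R 4.3.3. Spots flagged as outliers were set to missing in the dye concerned, spots of the same probe were averaged, and probes well above background in at least 4 of the 16 samples were kept. A probe needed at least 12 values in all and at least 2 in each group. Of 41012 probes for transcripts 21322 were matched to a gene symbol through the reference table of RefSeq accessions and symbols, and the remaining probes kept the name on the array. For each gene name the probe with the highest mean was tested, which gave 22907 genes from 27294 probes. All probes of named genes were also fitted, and the text names other probes that did not pass or went the other way where the tested one passed. Probe positions are those of the array annotation on rn4. Files were read with the R package data.table (version 1.17.8), probe sequences were searched with Biostrings 2.70.1, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

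The single-channel log2 intensities of all 16 samples were fitted in limma with the group and the dye as terms and the array as a random block (correlation within an array 0.569), and empirical Bayes moderation (11 residual and 4.05 prior degrees of freedom). P values are two-sided and were adjusted by the Benjamini-Hochberg method over the 22907 genes of a comparison, with a threshold of 0.05. The planned comparisons were knockdown against nontargeting, overexpression against not transduced, overexpression against nontargeting, nontargeting against not transduced, and the difference of the 2 same-slide comparisons. The groups, comparisons, model, gene lists and alternatives were chosen before the data were examined. Knockdown against not transduced, and overexpression against not transduced without the nontargeting group, were added after the data had been seen.

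The genes named for each comparison are, among genes past the threshold with a symbol and with every value of a group on the same side of every value of the other (a condition not set for the difference of comparisons), the 10 with the largest rise and the 10 with the largest fall. Where fewer than 3 genes passed, the 5 with the smallest p in each direction are given as values. Up to 4 measured members with the smallest p were named for each list described, and Jun always. Other list members are named as examples of members past the test and were chosen after their values were seen. The rule also named Prr7, for which no probe was found. A few further genes that these rules name are not reported here.

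The 25 gene lists covered activity-regulated genes, AP-1 factors, c-Jun or AP-1 targets, the JNK pathway with ubiquitin ligases of c-Jun, apoptosis, glutamate receptors, the postsynaptic density, synaptic vesicles and active zones, ion channels, the unfolded protein and integrated stress responses, heat shock, NRF2 targets, the respiratory chain, cholesterol synthesis, interferon-stimulated genes, inflammation, proliferating cells, and markers of neurons, excitatory neurons, interneurons, astrocytes, oligodendrocytes, microglia, vascular cells and fibroblasts. They were tested in limma with cameraPR at a preset correlation of 0.01 and, in parallel, with camera at a correlation estimated for each list, with adjustment over the 25 lists of a comparison. Members were counted as risen or fallen past the gene test, over all genes and adjusted over the list alone.

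The replicate numbers of the groups were checked for pairing. After group means were removed, same-numbered samples of knockdown and nontargeting correlated at 0.137, 0.153, 0.253 and 0.201 over genes, all above 0.1, and all 8 samples correlated best with their own number. The number also fixes the dye and the order of the arrays, and with dye means removed as well the values were 0.138, 0.0784, 0.149 and 0.074, with 4 of 8 samples closest to their own number. In the other comparisons at least 1 pair lay at or below 0.1 before dye means were removed. Nontargeting against not transduced, on different slides, still had 7 of 8 samples closest to their own number, and 5 of 8 with dye means removed. By the correlations alone the numbers would pair the knockdown and nontargeting samples. The numbers come from the labels, which name no shared animal, litter or day, and a pair cannot be told apart from a shared dye and array order, so the samples were not treated as pairs, and fits with the number as a block are given as alternatives.

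The pipeline was tested on 1 simulated set of 22907 genes in which 200 genes were changed and 25 others shifted by 0.5 as a list. For knockdown against nontargeting 145 of the 200 and 9 of the 25 were called along with 13 unchanged genes, and 37.3%, 85.1% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale were found. For the difference of comparisons 113 of the 200 and 4 of the 25 were called along with 13 unchanged genes, and the shares were 8.96%, 68.7% and 92.4%. In an earlier random draw the share at the smallest size was markedly lower, so it is imprecise. Alternatives covered the normalization, the filters, the block, the dye term, sample weights, the probe per gene, the deposited values, a minimum fold change, and leaving out each sample and each array. Other splits of the same samples were tested for each count of genes, with the correlation within an array estimated from a random draw of genes.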

Results

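Transcript levels were measured in primary neuron cultures prepared from the hippocampus of Sprague-Dawley rat embryos of embryonic day 18 to 19. The series concerns PRR7, a transmembrane adaptor protein of synapses, and the turnover of the transcription factor c-Jun. Cultures of 4 groups were compared: PRR7 knockdown by a lentiviral short hairpin RNA (shRNA), a lentiviral shRNA with no target, PRR7 overexpression from a lentivirus, and cultures that received no virus. Each group held 4 samples, which the study design names biological replicates. Agilent rat arrays with 41012 probes for transcripts were read in 2 dyes, and each of the 8 arrays carried 2 samples of the same group. The knockdown and nontargeting arrays lay on a shared slide, and the overexpression and not transduced arrays lay on the other. Knockdown against nontargeting and overexpression against not transduced were therefore compared within a slide, whereas in every other pair of groups the slide and the group cannot be told apart. Between 50.2% and 70.5% of probes per sample were well above background, and the median net signal per sample ranged from 73.2 to 150 intensity units. The number of arrays limits the precision. No probe named Prr7 and no probe held the shRNA target sequence, so the level of PRR7 was not read and the group labels were not checked on it.

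The nontargeting and knockdown cultures stood apart from each other and from the remaining cultures, while overexpression and not transduced cultures lay close together. On the first principal component of the 16 samples, which held 36.2% of the variance, the 4 nontargeting samples lay between 38.0 and 46.6, and the 4 knockdown samples between -3.01 and 0.21. The overexpression samples lay between -21.5 and -17.9 and the not transduced samples between -24.9 and -12.2. The second component held 22% and placed the knockdown samples between -35.0 and -33.1, with all other samples above 3.34. The SD across genes of the difference of group means was 0.454 (log2) between knockdown and nontargeting, 0.461 between nontargeting and not transduced, 0.369 between knockdown and not transduced, and 0.188 between overexpression and not transduced.

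**Figure D1:**
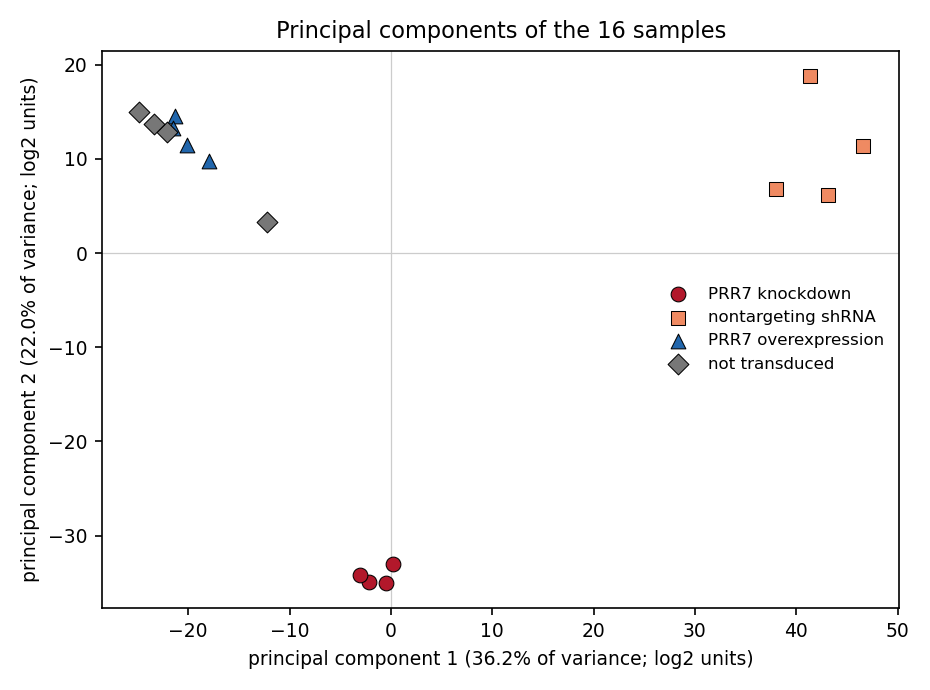
Principal components 1 and 2 (log2 units) of the 16 samples, 1 point per sample, marked by group. The nontargeting samples lie at 38.0 to 46.6 on the first component, the knockdown samples at -35.0 to -33.1 on the second, and the overexpression and not transduced samples overlap.

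Knockdown against nontargeting asked what changes when PRR7 is lowered in neurons that carry an shRNA. In knockdown cultures, genes of proliferating cells were higher and genes induced by neuronal activity were lower than in nontargeting cultures. With an estimated correlation the list of proliferating cells did not pass (adjusted p = 0.362), while that of activity-regulated genes did (0.0394). Mcm3, a subunit of the replicative helicase (probe on chromosome 9, 19538668 to 19538727, rn4), rose 8.59-fold, from a mean log2 intensity of 8.12 ± 0.24 to 11.23 ± 0.15 (SD, n = 4 samples per group). The SE of this log2 difference was 0.23 and the limma adjusted p was 3.68e-07. Fos, an AP-1 subunit and immediate early gene (chromosome 6, 109561099 to 109561158), fell 11.6-fold, from 12.56 ± 0.23 to 9.02 ± 0.29 (log2 difference -3.53 ± 0.30, adjusted p = 1.22e-06). The mean of Fos was 9.64 in overexpression and 9.71 in not transduced cultures, so its nontargeting level stood above the other 3 groups. For Mcm3 these means were 9.17 and 9.18, so its knockdown level stood above the other 3 groups and its nontargeting level below them.

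Of 22907 genes tested, 4922 passed the test in this comparison, 2390 higher and 2532 lower in knockdown, and 950 of them differed at least 2-fold. The other genes with the largest rises were Fabp3, a fatty acid carrier (log2 difference 2.74), Syt12, a synaptotagmin (2.73), Rab4b, a GTPase of endosomes (2.69), Ccne1, cyclin E1 (2.60; values in 3 samples of each group), Tcf19 (2.58) and the glutamate transporter Slc1a1 (2.48). They were followed by the mitochondrial protease Oma1 (2.34), Zmat3 (2.30; values in 2 samples of each group) and the zinc exporter Slc30a1 (2.21). The other genes with the largest falls were Mesp1 (-2.88), Ermp1 (-2.75), Ccn1 (-2.72), the proton pump subunit Atp6v0d1 (-2.67), the nuclear receptor Nr4a1 (-2.53), Txndc17 (-2.50), the kinase Sik1 (-2.36), Slc16a6 (-2.34) and Junb (-2.33). Several of these genes also changed strongly in nontargeting against not transduced cultures, in the opposite direction. There Fabp3 and Rab4b were among the largest falls, and Mesp1, Ccn1 (2.61), Nr4a1 and Sik1 among the largest rises. For these genes, as for Fos, the nontargeting level may account for much of the difference from knockdown. By the rule that chose them, all 20 genes, Mcm3 and Fos included, had every knockdown value on the same side of every nontargeting value. The same held for 4818 of the 4922 genes that passed. The adjusted p of the 20 genes ran from 3.91e-08 to 5.22e-05. For Ermp1 (chromosome 1, 233327344 to 233327403) the knockdown group stood apart, with a mean of 7.78 ± 0.16 against 10.53 ± 0.25 in nontargeting, 10.21 ± 0.27 in overexpression and 10.19 ± 0.10 in not transduced cultures. This rests on 1 of 2 probes, since the other showed no such fall (-0.18, adjusted p = 0.271). Atp6v0d1 (chromosome 19, 35342854 to 35343006) had the same arrangement, at 12.14 against 14.81, 14.60 and 14.59, with values in 2 nontargeting and 3 not transduced samples.

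**Figure D2:**
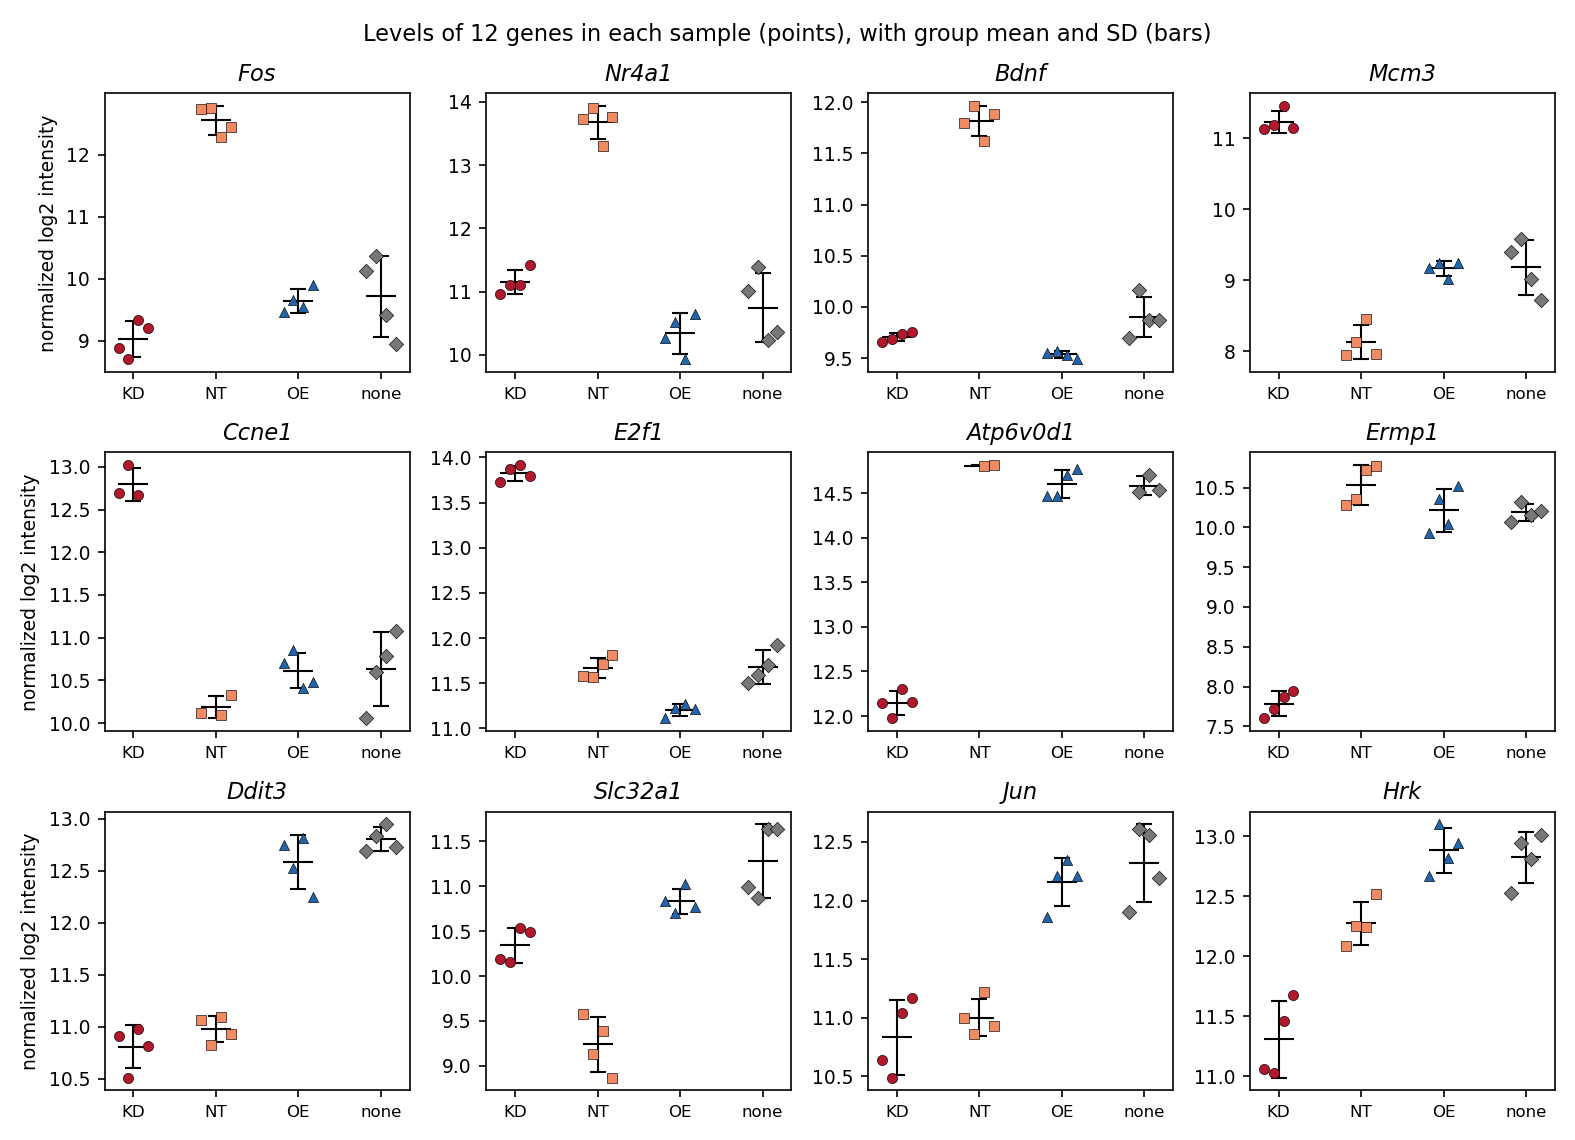
Normalized log2 intensity of the tested probe of 12 genes in knockdown (KD), nontargeting (NT), overexpression (OE) and not transduced (none) cultures, 1 point per sample, with bars for the group mean and SD. Fos, Nr4a1 and Bdnf are highest in nontargeting cultures, Mcm3, Ccne1 and E2f1 are highest and Atp6v0d1 and Ermp1 lowest in knockdown cultures, and Ddit3, Jun and Hrk are lower in both shRNA groups, which share a slide.

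Among the 22 measured activity-regulated and immediate early genes, 15 fell and 2 rose (2 rose and 17 fell adjusted over the list alone), with a median log2 difference of -0.96. The list test gave an adjusted p of 1.76e-18, and adjusted p = 0.0394 with an estimated correlation. The members that fell included Bdnf, a neurotrophin (-2.11), Nr4a2 (-2.12), Dusp1, a phosphatase of MAP kinases (-1.99), Inhba (-1.72), Arc (-0.92) and Npas4 (-0.85), and the 2 counted as risen were Egr1 (0.98) and Homer1, whose tested probe rose (1.77) while its other probe fell (-1.58, adjusted p = 0.000271), so its direction is not known. The tested Homer1 probe was one of 63 that hold the bases CTAACTC, whose mean log2 difference was 0.36 here. Among 27 measured genes of proliferating cells, 15 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.55, adjusted p = 9.27e-09, and adjusted p = 0.362 with an estimated correlation). They included Mcm6 (2.06), Cdk1, a mitotic kinase (2.04), Ccna2, cyclin A2 (1.74), Top2a (1.13, and 0.18 at a further probe that did not pass) and Mcm5 (1.01). Of markers of cells that can divide in such cultures, 4 of 19 for astrocytes rose and 1 fell, and 3 of 12 for oligodendrocytes rose and 0 fell. Neither list passed (adjusted p = 0.245 for each), and 2390 of all 22907 genes rose.

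Genes of glutamate signalling were higher in knockdown than in nontargeting cultures. Of 24 ionotropic and metabotropic glutamate receptors 11 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.32, adjusted p = 7.19e-05, and adjusted p = 0.0394 with an estimated correlation). Grm5 (1.31), the AMPA receptor subunits Gria2 (2.38-fold) and Gria3 (1.16) and the NMDA receptor subunit Grin2a (1.10) rose, and the NMDA receptor subunit Grin2c fell (-1.32). In nontargeting against not transduced cultures 9 of the 24 receptors were lower and 3 higher, with Gria2 at -1.13 and Grm5 at -1.20. Overexpression against nontargeting showed similar rises of Gria2 (1.37) and Grm5 (1.28). A low nontargeting level may therefore account for most of the rise of these 2 genes, though both of these comparisons span the slides. Of 25 postsynaptic density genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.00311, and adjusted p = 0.462 with an estimated correlation). The scaffolds Shank3 (1.29) and Dlgap3 (0.93) and Cacng3, an auxiliary AMPA receptor subunit (0.90), rose, and Shank1 fell (-0.63). Homer1 is counted as risen in this list too by its tested probe (1.77), although its other probe fell (-1.58). Genes of the unfolded protein and integrated stress responses were lower, with 7 of 23 measured members falling and 0 rising (9 and 0 adjusted over the list alone, median -0.43, adjusted p = 0.00871, and adjusted p = 0.244 with an estimated correlation). They included Ppp1r15a (-1.46), Herpud1 (-0.99), Dnajb9 (-0.90) and Hsp90b1 (-0.70), the last 3 of which act in folding or degrading proteins of the endoplasmic reticulum. The other Dnajb9 probe did not pass (-0.44). Of 23 cholesterol synthesis genes 4 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.31, adjusted p = 0.0444, and adjusted p = 0.569 with an estimated correlation), namely Stard4 (1.54), Fdft1 (0.93), Nsdhl (0.61) and Pmvk (0.50). With the replicate number as a block this list had an adjusted p of 0.0774, and Pmvk lost its call in 25 of 37 alternatives.

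Jun, which encodes c-Jun, did not pass the test in this comparison, with a log2 difference of -0.17 ± 0.27 (adjusted p = 0.730) and a knockdown mean of 10.83 ± 0.32. Its probe lies on chromosome 5, 115358764 to 115358823. The arrays measure its transcript and not the protein or its ubiquitination. Of 15 measured AP-1 transcription factors 4 fell, among them Fos, Junb and Mafg (-0.76), and Maf rose (0.70). Adjusted over the list alone 5 fell and 1 rose, with a median of -0.17, an adjusted p of 0.0323, and adjusted p = 0.483 with an estimated correlation. The other Mafg probe did not pass (-0.35). Of 32 genes described as c-Jun or AP-1 targets 4 rose and 8 fell (5 and 9 adjusted over the list alone, median -0.12, adjusted p = 0.317). The members that fell included Dusp1, Ptgs2 (-0.92) and the cell death activator Hrk (-0.97), and Ccna2 rose. Of 20 genes of the JNK pathway and of ubiquitin ligases for c-Jun 6 rose, among them Map3k10 (1.24), Cul1 (0.92) and Dusp16 (0.81), and 2 fell, among them Csk (-0.72; 6 and 2 adjusted over the list alone, adjusted p = 0.109). The other probes of Map3k10 (0.08) and Csk (0.35) did not pass.

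Markers of other cell types and further pathways did not pass as lists in this comparison. Of 15 markers of inhibitory interneurons 7 rose, such as Slc32a1, the vesicular transporter of GABA (1.10), and Dlx5 (1.03), and 2 fell, with Calb2 at -1.67 (median 0.45, adjusted p = 0.116). Astrocyte markers (4 rose, with Slc1a3 at 1.16, and 1 fell of 19, adjusted p = 0.245) and oligodendrocyte markers (3 rose of 12, adjusted p = 0.245) did not pass. Excitatory neuron markers (1 rose, Nrgn, and 1 fell, Wfs1, of 16, adjusted p = 0.544) and neuronal markers (3 rose and 2 fell of 15, adjusted p = 0.761) did not pass. Microglial markers (1 rose of 12, Lyz2 at 1.47, adjusted p = 0.544), fibroblast markers (1 rose and 1 fell of 11, adjusted p = 0.982) and vascular markers (1 rose and 1 fell of 8, adjusted p = 0.567) did not pass either. The adjusted p was 0.222 for apoptosis regulators (6 rose, with Diablo at 1.32, and 2 fell of 24) and 0.242 for ion channels (5 rose, with Kcna1 at 1.34, and 1 fell of 25). It was 0.245 for inflammatory genes (2 rose and 4 fell of 12), 0.355 for synaptic vesicle genes (4 rose and 1 fell of 26) and 0.355 for interferon-stimulated genes (4 rose and 1 fell of 25). It was 0.378 for the respiratory chain (1 rose and 3 fell of 28), 0.544 for heat shock genes (1 rose, Cryab at 1.65, and 2 fell of 11, with Hspb1 at -2.33) and 0.867 for NRF2 targets (1 rose and 3 fell of 10). Adjusted over the list alone, these counts changed to 8 risen and 3 fallen interneuron markers, 5 and 1 astrocyte markers, 4 and 3 neuronal markers, and 0 and 1 excitatory markers. They changed to 8 and 1 ion channels, 6 and 3 apoptosis regulators, 4 and 3 synaptic vesicle genes, 1 and 3 heat shock genes, and 2 and 3 NRF2 targets. The median and the mean differed in sign for NRF2 targets (0.06 and -0.11), neuronal markers (0.02 and -0.01), fibroblast markers (0.00 and -0.05) and microglial markers (-0.04 and 0.11).

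The test used limma on single channels with the array as a random block. A fit of the 8 samples of this slide alone gave 4152 genes, 3805 of them shared with the count above. Taking each array as 1 value lowered the count to 3075, leaving out either knockdown array lowered it to 2883 or 3110, and a 1.5-fold minimum lowered it to 3112.

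Knockdown was also compared with not transduced cultures, a comparison added after the data had been seen because the nontargeting group stood apart; here the slide and the group cannot be told apart. Genes of proliferating cells were slightly higher as a list in this comparison as well, though not with an estimated correlation (adjusted p = 0.690), whereas the activity-regulated genes did not pass as a list. In all, 2320 genes passed, 1113 higher and 1207 lower in knockdown, and 1112 of the 2320 also passed against nontargeting in either direction. The genes with the largest rises were Zcwpw1, a histone reader of meiosis (3.37), Timeless, a protein of the replication fork (2.71), Golph3 (2.35), Stk25 (2.31), Ccne1 (2.21), Mcm6 (2.19), Tcf19 (2.15), E2f1, a transcription factor of S phase entry (2.15), Mcm3 (2.05), and Dut, which keeps uracil out of DNA (1.98). The nontargeting means of Zcwpw1 (10.53) and Timeless (9.35) lay between those of knockdown (11.96 and 11.22) and of not transduced cultures (8.59 and 8.51). The largest falls were Atp6v0d1 (-2.45), Ermp1 (-2.40), Rab9b (-2.01), the stress-induced transcription factor Ddit3 (3.99-fold lower), Marchf8 (3.99-fold lower), Txndc17 (-1.98), Trib3 (-1.93), Mdh2 (-1.88; values in all 4 samples of both groups), Ubxn2a (-1.80) and a further proton pump subunit, Atp6v0a1 (-1.75; values in 2 not transduced samples). Their adjusted p ran from 8.21e-07 to 0.000368, and those of the rises from 1.23e-08 to 0.0438, the highest for Golph3. Further probes of Ermp1 (-0.05), Marchf8 (-0.32) and Ubxn2a (-0.14) did not pass.

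Of the 27 genes of proliferating cells 8 rose and 0 fell against not transduced (8 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.00116, and adjusted p = 0.690 with an estimated correlation). Of 22 activity-regulated genes 2 rose, among them Arc (0.46), and 4 fell, among them Ier2 (-1.34), Dusp1 (-1.05) and Junb (-0.90), with a median of 0.00 (2 and 4 adjusted over the list alone, adjusted p = 0.572). Of 23 genes of the unfolded protein and integrated stress responses 11 fell and 0 rose (15 and 0 adjusted over the list alone, median -0.68, adjusted p = 2.55e-13, and adjusted p = 0.0233 with an estimated correlation). They included Ddit3, Trib3, Ppp1r15a (-1.36) and Atf6 (-0.94). Interneuron markers fell in 7 of 15 and rose in 0 (8 and 0 adjusted over the list alone, adjusted p = 2.88e-05, and adjusted p = 0.141 with an estimated correlation). Glutamate receptors rose in 4 of 24 and fell in 1 (adjusted p = 0.0146, and adjusted p = 0.141 with an estimated correlation) and cholesterol synthesis genes rose in 2 of 23 (adjusted p = 0.0146, and adjusted p = 0.617 with an estimated correlation). The c-Jun or AP-1 targets fell in 7 of 32 and rose in 3, with Hrk at -1.52 and Ccnd1, cyclin D1, at 1.88 (8 and 3 adjusted over the list alone, adjusted p = 0.0336, and adjusted p = 0.495 with an estimated correlation). Jun was lower in knockdown than in not transduced cultures (log2 difference -1.48 ± 0.27, adjusted p = 0.00299).

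Overexpression against not transduced asked what added PRR7 changes, with the vector itself as part of the difference, because no empty overexpression vector was among the 4 groups. These groups were the closest pair, and 1 gene of 22907 passed with limma, against 901 at an unadjusted p under 0.05. Eftud2, a GTPase of the spliceosome (chromosome 10, 92012348 to 92012407), was higher in overexpression, with a log2 difference of 1.71 ± 0.17 (3.27-fold, adjusted p = 0.00794) at the tested probe, whereas its other probe showed no change (-0.04, adjusted p = 1.00). Its means were 12.89 in the 2 overexpression samples with a value and 11.20 in the 3 not transduced samples with a value. The means were 13.05 in knockdown and 12.84 in nontargeting cultures, so the not transduced group stood apart. In the fit of this slide alone 0 genes passed and Eftud2 had an adjusted p of 0.633. With the replicate number as a block 0 genes passed and Eftud2 had an adjusted p of 0.0546, and over all its alternatives the adjusted p ran from 0.000174 to 0.633.

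The other genes with the smallest p did not pass and are given as values. Ccndbp1 (0.83), Nampt (0.82), T2 (1.08, at least 2.04-fold, dim in every group but overexpression) and Zranb2 (0.55) had higher values in overexpression. The neurofilament gene Nefh (-0.88), Nit1 (-0.65), Mustn1 (-0.84), Lgi2 (-0.76) and Brinp1 (-0.65) had lower values, and the adjusted p of these 9 genes ran from 0.321 to 0.627. Jun had a log2 difference of -0.16 ± 0.27 (adjusted p = 1.00). Activity-regulated genes lay slightly lower as a list (median -0.24; 0 of 22 members past the test, and 1 lower adjusted over the list alone, adjusted p = 1.29e-05, and adjusted p = 0.368 with an estimated correlation), with values of -0.45 for Arc and -0.46 for Junb. Astrocyte markers lay slightly higher (median 0.21; 0 of 19 members, adjusted p = 0.0120, and adjusted p = 0.681 with an estimated correlation). Neuronal markers lay slightly lower (median -0.12; 0 of 15 members, and 1 lower adjusted over the list alone, adjusted p = 0.0308, and adjusted p = 0.671 with an estimated correlation). The remaining 22 lists did not pass, with adjusted p from 0.104 to 0.856, the glutamate receptor (0.400), AP-1 (0.563) and proliferating cell lists (0.563) among them. Adjusted over the list alone, 2 interneuron markers and 1 gene each of the vascular, fibroblast and c-Jun target lists were lower. Leaving out an overexpression array raised the count of genes to 38 or 41, and leaving out a not transduced array raised it to 6 or 33.

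Nontargeting against not transduced asked what the control virus with its shRNA changes; here the slide and the group cannot be told apart. Activity-regulated genes were higher and interneuron genes lower in nontargeting cultures, though neither list passed with an estimated correlation (adjusted p = 0.148 for each). Of 22907 genes 5153 passed, 2648 higher and 2505 lower. The largest rise was that of Nr4a1 (chromosome 7, 140020442 to 140020501), which was 7.62-fold higher (log2 difference 2.93 ± 0.23, adjusted p = 1.08e-06). It was followed by Fos (2.84), Mesp1 (2.76), Ccn1 (2.61), Sik1 (2.40), the small heat shock protein Hspb1 (2.33), the RNA-binding protein Khdrbs2 (2.26), the carbonic anhydrase Car4 (2.26), Stk25 (2.23) and Golph3 (2.20, adjusted p = 0.0340). Golph3 lost its call in 11 of 37 alternatives. Among the largest falls were Ifi27l2b (-2.80), Rab4b (-2.66), the secreted synaptic ligand Nxph1 (-2.65), Fabp3 (-2.49), the glutamine synthetase gene Glul (-2.40), Jam2 (-2.23), Ywhab (-2.19), Igfbp5 (-2.19) and Pea15 (-2.16). The other Ifi27l2b probe did not pass (0.08). Activity-regulated genes rose in 14 of 22 and fell in 3 (16 and 3 adjusted over the list alone, median 0.89, adjusted p = 5.68e-16, and adjusted p = 0.148 with an estimated correlation), with Bdnf at 1.91 and Arc at 1.37. Homer1 is counted as fallen by its tested probe (-1.49), although its other probe rose (0.79). Interneuron markers fell in 9 of 15 and rose in 0 (10 and 0 adjusted over the list alone, median -0.86, adjusted p = 1.05e-07, and adjusted p = 0.148 with an estimated correlation), including Slc32a1 (-2.04), Dlx5 (-1.54) and Pvalb, parvalbumin (-1.15).

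Genes of proliferating cells fell in 10 of 27 in nontargeting cultures and rose in 0 (12 and 0 adjusted over the list alone, median -0.41, adjusted p = 0.00851, and adjusted p = 0.536 with an estimated correlation), with Mcm3 at -1.06 and Rrm2 at -1.05, although their other probes did not pass (-0.32 and -0.18). Stress response genes fell in 7 of 23 and rose in 2 (12 and 2 adjusted over the list alone, median -0.37, adjusted p = 0.0391, and adjusted p = 0.404 with an estimated correlation), with Ddit3 at -1.83, Atf3 at -1.55 (values in 2 not transduced samples) and Trib3 at -1.22. With the replicate number as a block this list did not pass (adjusted p = 0.0681). Jun was lower (-1.32 ± 0.27, adjusted p = 0.00297). The other 21 lists did not pass, with adjusted p from 0.0705 to 0.989. A fit of these 8 samples alone gave 3232 genes, taking each array as 1 value gave 3278, and a 1.5-fold minimum gave 3094.

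Overexpression against nontargeting compared the 2 groups with different transgenes across the slides, so the slide and the group cannot be told apart here either. Activity-regulated genes were lower and interneuron and astrocyte markers higher in overexpression, though none of these lists passed with an estimated correlation (adjusted p = 0.0736, 0.222 and 0.569). Of 22907 genes 5215 passed, 2381 higher and 2834 lower. Among the largest rises were Nxph1 (2.83 ± 0.19, adjusted p = 3.34e-07), Igfbp5 (2.70), Glul (2.62), Jam2 (2.56; values in 2 overexpression samples), Ifi27l2b (2.55), Rab4b (2.42), Slc13a3 (2.25), Pea15 (2.19) and Fabp3 (2.16). The other Ifi27l2b probe did not pass (0.14). The largest falls were Nr4a1 (-3.34), Fos (-2.92), Mesp1 (-2.90), Ccn1 (-2.78), Car4 (-2.45), Sik1 (-2.39), Stk25 (-2.36, adjusted p = 0.0139), Bdnf (-2.28), Khdrbs2 (-2.28) and Egr4 (-2.23). Activity-regulated genes fell in 16 of 22 and rose in 2 (16 and 2 adjusted over the list alone, median -1.15, adjusted p = 1.35e-24, and adjusted p = 0.0736 with an estimated correlation). Homer1 is counted as risen by its tested probe (1.37), although its other probe fell (-1.20). Interneuron markers rose in 8 of 15 and fell in 0 (8 and 0 adjusted over the list alone, adjusted p = 4.29e-06, and adjusted p = 0.222 with an estimated correlation), with Gad2 at 1.83. Astrocyte markers rose in 9 of 19 and fell in 0 (10 and 2 adjusted over the list alone, adjusted p = 0.0172, and adjusted p = 0.569 with an estimated correlation), with S100b at 1.58 and Hes5 at 1.41. Genes of proliferating cells rose in 7 of 27 and fell in 0 (10 and 0 adjusted over the list alone, adjusted p = 0.0172, and adjusted p = 0.551 with an estimated correlation). Glutamate receptors rose in 8 of 24 and fell in 4 (8 and 4 adjusted over the list alone, adjusted p = 0.0392, and adjusted p = 0.398 with an estimated correlation), and with the replicate number as a block this list did not pass (adjusted p = 0.0532). Jun was higher in overexpression (1.16 ± 0.27, adjusted p = 0.00676). Taking each array as 1 value gave 3323 genes, leaving out either overexpression array gave 3042 or 3113, and a 1.5-fold minimum gave 3081.

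**Figure D3:**
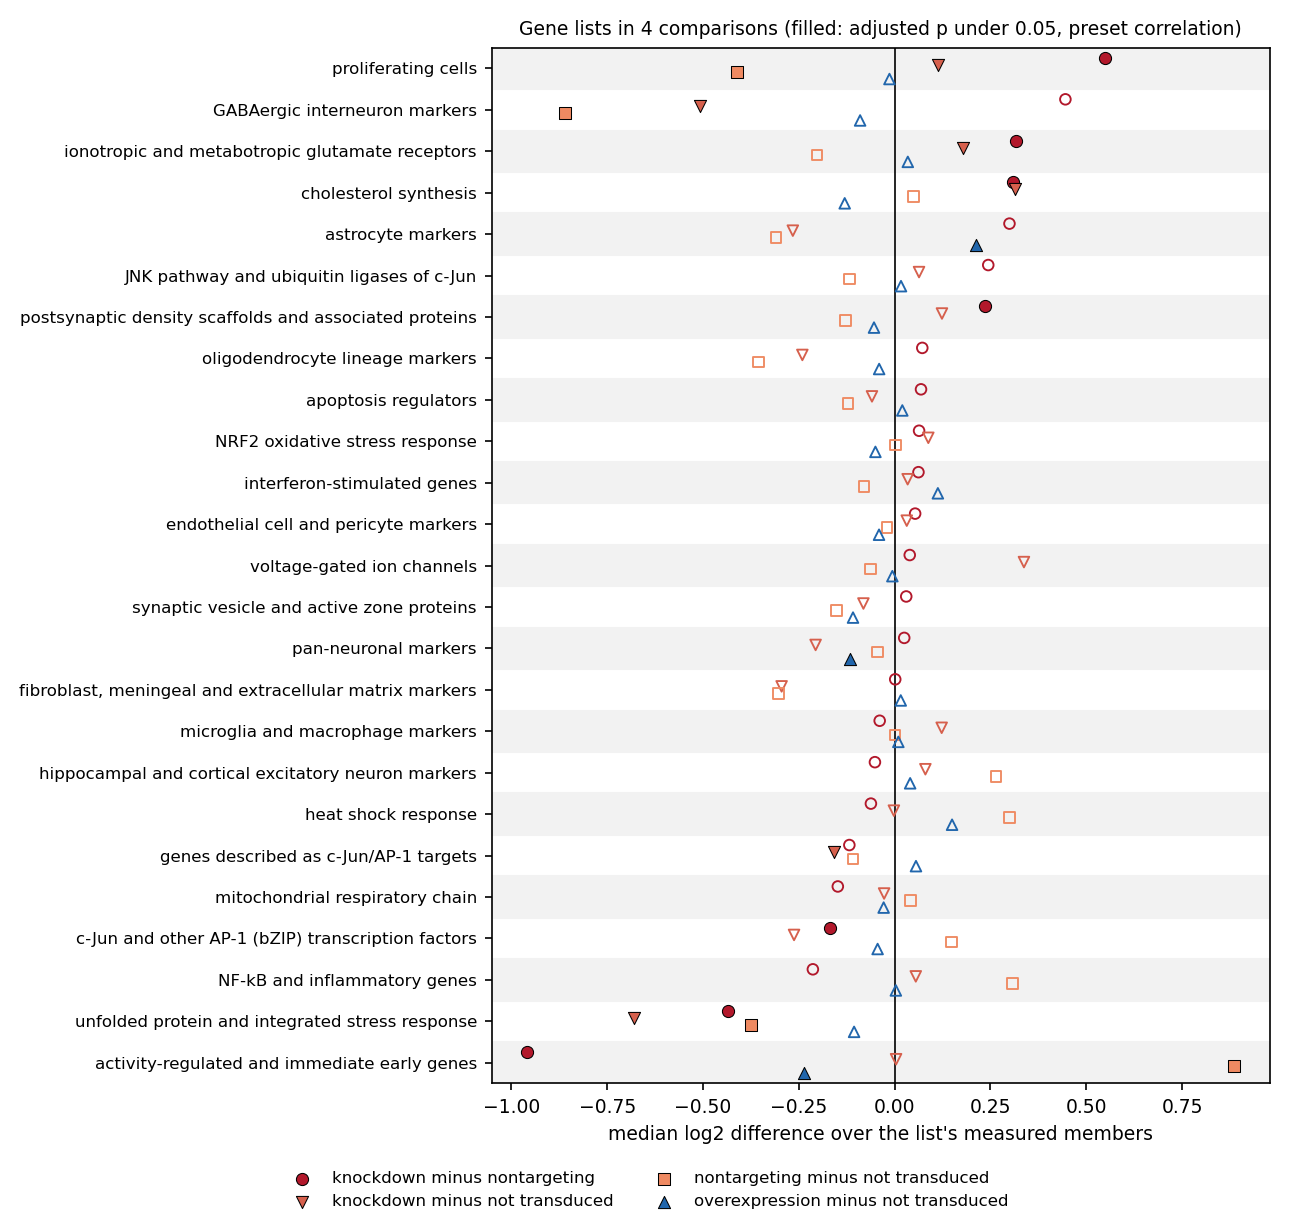
Median log2 difference of the measured members of each of 25 gene lists in 4 comparisons, with filled symbols where the list test with a preset correlation gave an adjusted p under 0.05. Activity-regulated genes lie at -0.96 in knockdown against nontargeting and at 0.89 in nontargeting against not transduced, and most overexpression medians lie close to 0.

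The knockdown effect (against nontargeting) minus the overexpression effect (against not transduced) compared the 2 same-slide effects; effects of the slide or of the position on it that add alike to both comparisons drop out of this contrast. The 2 effects have different controls, so the difference between nontargeting and not transduced cultures is part of it. For activity-regulated genes, whose median was 0.00 in knockdown against not transduced, it does not show an opposite action of lowering and raising PRR7. Genes of proliferating cells had higher and activity-regulated genes lower differences in knockdown than in overexpression, though neither list passed with an estimated correlation (adjusted p = 0.468 and 0.0767). Of 22907 genes 2267 passed, 1272 higher and 995 lower. The largest positive differences were Mcm3 (3.12 ± 0.32, adjusted p = 3.40e-05), Fabp3 (3.07), Syt12 (2.99), Rab4b (2.92), Tcf19 (2.72), E2f1 (2.63), Ccne1 (2.62), Slc1a1 (2.58), Oma1 (2.55) and Samd14 (2.37). The largest negative differences were Fos (-3.46 ± 0.42, adjusted p = 0.000113), Ermp1 (-2.77), Mesp1 (-2.74), Hspb1 (-2.70), Atp6v0d1 (-2.68), Ccn1 (-2.55), the inositol transporter Slc5a3 (-2.43), Sik1 (-2.36), the ubiquitin ligase Marchf8 (-2.32) and Txndc17 (-2.30). The other Ermp1 probe (-0.08) and 1 of 4 Samd14 probes (0.53) did not pass. Genes of proliferating cells were higher in 8 of 27 and lower in 0 (13 and 0 adjusted over the list alone, median 0.69, adjusted p = 2.53e-08, and adjusted p = 0.468 with an estimated correlation). Activity-regulated genes were lower in 9 of 22 and higher in 1 (12 and 1 adjusted over the list alone, median -0.69, adjusted p = 2.18e-10, and adjusted p = 0.0767 with an estimated correlation). Glutamate receptors (6 higher and 1 lower of 24, adjusted p = 0.00116, and adjusted p = 0.0767 with an estimated correlation) and postsynaptic density genes (7 higher of 25, adjusted p = 0.00116, and adjusted p = 0.490 with an estimated correlation) passed too. In the activity-regulated and postsynaptic lists Homer1 is counted as higher by its tested probe (1.89), although its other probe was lower (-1.17). Cholesterol synthesis genes (3 higher of 23, adjusted p = 0.0111, and adjusted p = 0.495 with an estimated correlation) and interneuron markers (4 higher, with Npy at 1.43, and 1 lower, Calb2 at -2.03, of 15, adjusted p = 0.0490, and adjusted p = 0.490 with an estimated correlation) also passed. Jun had a difference of -0.01 ± 0.38 (adjusted p = 0.995). Across genes, which are not independent replicates, the effects of knockdown and of overexpression had a Pearson r of -0.0335 and a Spearman rho of -0.0224, and with 1 gene called for overexpression the count of shared calls says nothing. Taking each array as 1 value lowered the count of genes to 948, and leaving out the array of knockdown replicates 1 and 2, of overexpression replicates 1 and 2 or of nontargeting replicates 1 and 2 gave 1460, 1492 or 3492.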

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

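The tests of the slide, of excitatory neurons, of dividing cells and of nontargeting as an unusual control were chosen after the results they measure had been seen, and so was the standard error used for the test of dimmer samples. In their first forms, the tests of the slide (with a bound of 0.5 times the list's own median in the single comparisons) and of dimmer samples (with the standard error of the median) decided nothing, so their outcomes below weigh less than planned ones. The test of dividing cells was extended to further comparisons after its first outcome had been seen. The standard errors of medians below were taken over the members of a list as if independent, and not over cultures or arrays.

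The effects of knockdown and overexpression differed, by a test of the difference itself, for 2267 genes. They differed also for 6 gene lists, with a median of -0.69 for activity-regulated genes, 0.69 for genes of proliferating cells, 0.36 for glutamate receptors, 0.39 for postsynaptic density genes, 0.41 for cholesterol synthesis and 0.67 for interneuron markers. With an estimated correlation 0 of these lists passed, with adjusted p of 0.0767 or more. The 2 effects have different controls, so the difference between these controls is part of each value.

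Activity-regulated genes were higher in nontargeting than in all other cultures, with a median of 0.89 ± 0.31 (SE) against not transduced. With an estimated correlation the list did not pass against not transduced (adjusted p = 0.148) or overexpression (0.0736), and passed against knockdown (0.0394). A slide or position effect adding alike to both same-slide comparisons would leave the median of their difference within 2 standard errors of 0. That median was -0.69 ± 0.33 and lies just beyond them. Its error takes the 22 members as independent, while their estimated correlation was 0.094 and would widen it, so the slide stays open. With the trend of the fold change on the signal level taken out, the median against not transduced was still 0.86. The arrays had already been aligned by normalization, which leaves little such trend, and the median part it gave was 0.05. Its removal could hardly have lowered the median, so the test cannot decide, and dimmer nontargeting samples stay open as a cause. A larger share of excitatory neurons stays open, with their 16 markers at a median of 0.26 ± 0.15, and so does an effect of the nontargeting virus or of its shRNA, for which no other test was run. The nontargeting group as a control may therefore account for part of the fall of these genes in knockdown against nontargeting, since their median against not transduced was 0.00 ± 0.16.

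Genes of DNA synthesis, a part of the list of proliferating cells, were higher in knockdown than in nontargeting and not transduced cultures, although with an estimated correlation the whole list did not pass in either (adjusted p = 0.362 and 0.690). An unusual nontargeting group would leave these 9 genes unchanged against not transduced, where they lay at 0.94 ± 0.33. A slide or position effect that adds alike would leave them near 0 in the difference of both same-slide comparisons, where they lay at 0.93 ± 0.36. The first comparison spans both slides and the second holds the nontargeting samples, so each argues against 1 cause only if the other is absent. Both causes together are not excluded. The errors also take genes as independent, while the whole list had an estimated correlation of 0.365. More dividing cells stay open. They would raise the other 18 genes of the list, called mitosis genes here, about as much as the DNA synthesis genes. These 18 are all members left after the DNA synthesis genes were taken out, and need not all act in mitosis. Against not transduced the mitosis genes lay at 0.0054 ± 0.14, with 1 of 18 risen against 7 of 9, but there the slide and the group cannot be told apart. Against nontargeting they lay at 0.35 ± 0.17, with 7 risen, beside 0.82 ± 0.37 and 8 risen for DNA synthesis, and in the difference at 0.44 ± 0.17, so these comparisons do not exclude it. Whether the change follows from the loss of PRR7 or from other targets of the shRNA was not tested for these genes.

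Other splits of the same samples were fitted for genes with no missing value, with the correlation within an array taken from a random draw of genes. In 10 further draws, added after a change of draw was seen to move the counts, the real split gave 3865 to 4044 genes for knockdown against nontargeting and 1862 to 2020 for the difference of both comparisons. For knockdown against nontargeting the real split gave 3950 genes and was the highest of 35 (1 of 35 as large), with 12 in the highest other split, so a random grouping of single samples can be excluded. The same holds for overexpression against nontargeting (3751 genes, 1 of 35, highest other 6) and for nontargeting against not transduced (3148 genes, 1 of 35, highest other 90). For overexpression against not transduced the real split gave 0 genes, so that all 35 of 35 splits give as many whatever the data and the count tests nothing. The highest other split, which kept arrays whole, gave 16. For the difference of both comparisons the real grouping gave 1903 genes and was the highest of 100 drawn (1 of 100), although the highest other gave 1741. The 2 samples of an array are correlated, and nearly all other splits part them. With arrays kept whole, each comparison of 2 groups has 2 other splits, too few for a test with the array as the unit.

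Single samples lay far from the other 3 of their group in 18 of 499 groups of values, where chance gives about 1 in 20. The gap to the nearest sample, as a share of the group's range, is given for each. In nontargeting cultures, replicate 4 was lowest for Glul (0.899), Junb (0.906) and Ccna2 (0.836) and highest for Csk (0.878), replicate 3 was lowest for Golph3 (0.859) and Ccnd1 (0.855), and replicate 2 was highest for Rab4b (0.838). In overexpression cultures, replicate 2 was highest for Atf6 (0.880) and lowest for Rrm2 (0.853), replicate 4 was highest for Gria2 (0.841) and lowest for Ppp1r15a (0.864), replicate 3 was lowest for Kcna1 (0.863) and replicate 1 for Wfs1 (0.887). In knockdown cultures, replicate 3 was highest for Mcm3 (0.857) and Tcf19 (0.872), and replicate 2 for Ywhab (0.913). In not transduced cultures, replicate 4 was lowest for Igfbp5 (0.901) and replicate 2 highest for Mdh2 (0.912). None of the sample quality values tested passed this limit. The limit marks single samples and cannot mark both samples of an array or of a dye. In nontargeting cultures, outlier spots made up 0.588% and 0.662% in replicates 1 and 2, which share an array. They made up 2.22% and 2.00% in replicates 3 and 4 on the other array.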

How the results depend on the processing

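Knockdown against not transduced and the fit without the nontargeting group were added after the data had been seen; the other alternatives were planned. The cause of the changes below was not tested, except where the alternative itself gives it. These cases are fewer independent values with array means and a stricter criterion with a minimum fold change. Leaving out an array leaves fewer samples, which may lower a count but does not account for the counts that rose. With samples taken as independent (no array block) the counts were 8287 genes for knockdown against nontargeting, 34 for overexpression against not transduced, 9156 for overexpression against nontargeting, 9121 for nontargeting against not transduced and 5293 for the difference of comparisons. With array means they were 3075, 0, 3323, 3278 and 948 in the same order. Sample weights gave 11058, 9157, 8113 and 5725 genes for all but overexpression against not transduced, and a 1.5-fold minimum gave 3112, 3081 and 3094 for knockdown against nontargeting, overexpression against nontargeting and nontargeting against not transduced. With only the groups compared in the fit the counts were 0 for overexpression and 3232 for nontargeting against not transduced. For overexpression against not transduced the Agilent processed signal gave 2 genes, the deposited log2 values 4, and the fit without the nontargeting group 0. Not transduced as the control of knockdown gave 2320 genes.

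The replicate block, with the replicate number in place of the dye, gave 5683 genes for knockdown against nontargeting, 0 for overexpression against not transduced, 6183 for overexpression against nontargeting, 6079 for nontargeting against not transduced and 2849 for the difference. It ended the call of Eftud2 (adjusted p = 0.0546) and of 3 list tests: cholesterol synthesis in knockdown against nontargeting (adjusted p = 0.0774), glutamate receptors in overexpression against nontargeting (0.0532) and stress responses in nontargeting against not transduced (0.0681). Of the 25 passing list tests and 167 results for named genes run with it, all in planned comparisons, no other call changed. Knockdown against not transduced and other list members were not run with it. Leaving out each sample in turn gave 4290 to 5029, 0 to 2, 4358 to 5533, 4238 to 5409 and 1893 to 2472 genes in that order. The 0 came without not transduced replicate 3 or overexpression replicate 2, and the 2 without overexpression replicate 3. Leaving out knockdown array 1 or 2 gave 2883 or 3110 genes for knockdown against nontargeting, and leaving out any other array gave up to 5689. For overexpression against not transduced the counts were 0 without knockdown array 2, 6 or 33 without not transduced array 1 or 2, and 38 or 41 without overexpression array 1 or 2. For overexpression against nontargeting they were 3042 or 3113 without overexpression array 1 or 2, and up to 5883 without another array. For the difference they were 1460 without knockdown array 1, 3492 without nontargeting array 1 and 1492 without overexpression array 1.

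Over the planned comparisons 25 list tests passed with the preset correlation and 2 with an estimated correlation, activity-regulated genes and glutamate receptors in knockdown against nontargeting; with the other alternatives 21 to 31 passed. Of 300 values of these 25 lists 247 stayed past the threshold, 53 no longer passed and 0 changed direction. Of 6120 values of 167 results for named genes 6023 stayed on their side of the threshold, 84 no longer passed and 13 newly passed. Where the value passed in either fit, 0 changed direction. A change of sign between values that did not pass was not counted. The calls lost most often were those of Pmvk in knockdown against nontargeting (25 of 37 alternatives), Golph3 in nontargeting against not transduced (11), Nsdhl in the difference of comparisons (7) and Eftud2 in overexpression against not transduced (6). The r between the effects of knockdown and overexpression ranged from -0.0425 to -0.0164.

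The deposited log2 values moved the median of all genes by over 0.1, to 0.16 in knockdown against nontargeting, -0.16 in overexpression against not transduced, -0.21 in overexpression against nontargeting and 0.32 in the difference, and with them 78.5% of calls in knockdown against nontargeting were higher in knockdown, against 48.6%, and 89.7% of calls in the difference were positive, against 56.1%. The Agilent processed signal moved it to -0.11 in knockdown against nontargeting, -0.15 in overexpression against nontargeting and 0.14 in nontargeting against not transduced. Counts of rises and falls are relative to a normalization that holds these medians near 0. Of 3554 genes with more than 1 probe 1267 were called by a probe in knockdown against nontargeting, 350 of them the same way by all their probes and 14 in both directions, so most of these calls rest on some of the probes. No alternative was run for the level of PRR7, which has no probe. Signal over background limits dim genes: 9259 probes were well above background in no sample and were left out.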

Other observations

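The comparison of knockdown with both controls, the seed site in comparisons other than those of knockdown, and the search over all heptamers were chosen after results had been seen.

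Against both controls together, 442 genes were higher and 547 lower in knockdown. Independent lists of the same sizes would share 116.1 and 133.4, but both comparisons use the same knockdown samples, and how far this raises the shared counts is not known. With separate knockdown arrays for the 2 controls, 191 or 184 genes were higher and 232 or 261 lower, with 1 knockdown array in each comparison, so the drop cannot be put down to the sharing alone. Among the genes higher than both controls were Mcm3, Mcm6, Ccne1, Tcf19 and E2f1. Among those lower than both were Ermp1 (at 1 of its 2 probes), Atp6v0d1, Txndc17, the phosphatase subunit Ppp1r15a and the cell death activator Hrk. The log2 difference of Hrk was -0.97 against nontargeting and -1.52 against not transduced cultures.

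Further lists did not pass in nontargeting against not transduced cultures, and single members that did are given as values. Excitatory neuron markers rose in 6 of 16 and fell in 1, with Neurod1 at 0.91 and Fezf2 at 0.81 (median 0.26, adjusted p = 0.109). Oligodendrocyte markers fell in 3 of 12, with Bcas1 at -1.43, and -0.77 at a further probe that did not pass (adjusted p of the list = 0.0705). Glutamate receptors fell in 9 of 24 and rose in 3, with Grm5 at -1.20 and Gria2 at -1.13 (adjusted p = 0.109). The astrocyte gene Glul fell (-2.40), and astrocyte markers fell in 3 of 19 and rose in 0 (adjusted p = 0.150). Fibroblast markers fell in 4 of 11 and rose in 0 (median -0.30, adjusted p = 0.140).

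A hypothesis on the genes lower in knockdown is that the shRNA may lower transcripts other than its target through the 7 bases that pair with the seed of its guide (bases 2 to 8). The 114 tested probes that hold this site, ATGTCTA, lay lower than the other probes by a mean log2 difference of -0.23 ± 0.05 (SE) in knockdown against not transduced and of -0.16 ± 0.05 against nontargeting. This prediction was written before its result was seen, with a bound of 0.1. In the comparisons without knockdown the difference was 0.01 ± 0.02 (overexpression against not transduced), 0.08 ± 0.04 (overexpression against nontargeting) and -0.07 ± 0.04 (nontargeting against not transduced). Of the 547 genes lower in knockdown than in both controls 18 had the site in their probe, 3.29% against 0.429% of the other genes (two-sided Fisher's exact test, p = 2.32e-10). They included Shmt2 (-0.65 against nontargeting and -1.72 against not transduced), Dusp3 (-1.40 and -1.27), Rab10 (-1.09 and -1.09) and Hbp1 (-0.92 and -1.08). A further Dusp3 probe did not pass against either control (0.02 and -0.04), and further probes of Rab10 and Hbp1 did not pass against nontargeting, nor did 1 of Rab10 against not transduced. Probes of 60 bases were searched and not whole transcripts, so the share of the 547 genes that this could reach is not known, and probes of related transcripts are not independent.

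Over 11091 heptamers found in at least 40 probes, ATGTCTA had the lowest z of the mean in knockdown against not transduced (-6.61). In knockdown against nontargeting it was not among the 3 lowest, and 0.184% of 9243 heptamers found in a similar number of probes had a lower mean. In nontargeting against not transduced, CTAACTC had the lowest z (-6.01, mean -0.34 over 63 probes) and GTCTTCC the highest (6.09, mean 0.26 over 125 probes). In knockdown against nontargeting their means were 0.36 (z = 6.41, the highest) and -0.31 (z = -7.58, the lowest). The nontargeting samples enter this comparison with the opposite sign, so the turn is not a second observation. The probes with CTAACTC had a median of 0.01 in knockdown against not transduced, with 33 higher and 30 lower. Their median was 0.29 in overexpression against nontargeting. The 21 probes with GTCTTCCC, an extension of GTCTTCC taken from these same data, had a median of 0.93 in nontargeting against not transduced, 19 of them higher. Their median was -1.19 in knockdown against nontargeting, 19 of them lower, and -0.61 in overexpression against nontargeting. In knockdown against not transduced it was -0.13, with 7 higher and 14 lower. These z values assume independent probes. Among the genes named by the rule, Homer1 had a probe with CTAACTC, Mapk8ip3 a probe with GTCTTCC, and Dcn and Tm7sf2 probes with ATGTCTA.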
